A study of Mus musculus with 16 samples.

How the data were processed

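RNA was measured in 16 libraries from whole mouse cortex at postnatal day 7.5, each an IP of HA-tagged ribosomes or the input lysate it was taken from. Per the labels' protocols, RNA underwent single primer isothermal amplification and was sequenced as single-end reads on an Illumina NextSeq instrument. Per the submitters' processing notes, Trimmomatic, STAR and featureCounts were used with the mouse build GRCm38.p6, and DESeq2 was used by the authors. No versions are given there.

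The first deposited table holds, for 12011 rows, the authors' mean normalized count of each group, which is a signal value with no n or spread, with the authors' log2 fold change of IP over input in each genotype and its unadjusted p-value. After 2 repeated rows were dropped, 12009 genes remained, 12008 with an Ensembl identifier, of which 12007 matched GENCODE M21. Each gene's highest group mean was at least 50.0. The second deposited table holds 447 genes with the authors' log2 fold change and p-value of mutant over heterozygous IP, and its group means equal those of the first. Coordinates are from GENCODE M21, which is on the authors' build. The share of reads per gene, the raw depth and all values per library are not used here, because the columns are group means.

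The linear model on values per library that was planned before the data were examined could therefore not be fitted. In its place, a Wald test was reconstructed. The SE of each gene was taken as the size of the authors' log2 fold change divided by the normal quantile of its p-value. Fold changes between other groups were formed from the group means plus a pseudocount of 1 and multiplied by the shrinkage that the authors' own fold changes show at that SE, read in 40 bins of SE. The variance of a comparison of 2 groups within a fraction was the mean of the squared SEs of both genotypes, which assumes equal variance in IP and input. The difference of 2 genotypes' IP to input effects had the sum of their squared SEs as its variance. Genes entered with a mean of at least 10, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. A gene was called in the IP against input when it passed in all 3 genotypes in 1 direction. This replaced the planned mean of the 3 genotypes as 1 contrast, which is given as an alternative.

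The SEs of the reconstruction were checked on the second table, whose fold changes and p-values were not used to build it. Across the listed genes the SEs had a median ratio of 0.999. The log2 fold changes differed with an SD of 0.034, but both tables hold the same group means, so that agreement was largely fixed in advance and tests only the shrinkage. At the authors' limits as seen from their values, the reconstruction gave 453 genes, of which 431 were among the 447, a count that also rests on the shared means. The SE check covers the mutant to heterozygous IP comparison only. If the authors' test used 1 spread per gene for all groups, that agreement was also largely fixed in advance. It then does not test equal variance in IP and input. All comparisons within a fraction therefore rest on the equal-variance assumption. The test was also run on simulated data for 12009 genes. Simulated genes were independent, with equal spread in IP and input and with SEs taken from the reconstruction. The shares called therefore hold under the assumptions of the test and do not check them. In the mutant to heterozygous IP comparison it called 14% of genes changed by a log2 fold of 1, 70% at 2, 78% at 3 and 94% at 4, and 3 of 11809 unchanged genes. For the difference of IP and input effects it called 2%, 54%, 62% and 78%. The changes were planted in mutant IP alone, and in the mutant to heterozygous input comparison, where none was planted, 0 of the 12009 genes were called. The share of true input changes that the test finds was therefore not simulated. The implied SEs were near equal in mutant and heterozygous cortex (median ratio 1.003, SD 0.0054), and in wild type their median ratio to heterozygous was 1.18. They behave as if each gene had 1 spread shared by the groups. P-values therefore do not measure the spread within a group of 2 or 3 libraries, or within a fraction.

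Gene lists were fixed before the data were examined and tested with cameraPR of limma 3.58.1 in R 4.3.3 at a preset correlation of 0.01, on the reconstructed z values, or for IP against input on their sum over genotypes. A correlation could not be estimated from group means, so 0.05 was added as an alternative after the data were seen. Lists of fewer than 5 members were not tested. No gene of the mitochondrially encoded list was in the table. Listed genes were counted in each list with Fisher's exact test against the 11340 genes with a mean of at least 50 in either IP group.

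Named genes follow a rule fixed before the data were examined. It takes allele genes, among them Mapk3, Slc32a1 and Rpl22, up to 8 genes with the largest changes past the threshold in each direction, and up to 4 members of each list that passed, or else the 2 with the highest level. Its condition that libraries do not overlap could not be applied. Some genes that the rule takes are not reported here. Cartpt, Pdlim3, Egr2, Adam4, Etv5, Spred2, Sst, Bdnf, Nrn1, Rgs2, Crh, Slc30a5 and Cre were named in at least 1 comparison after their values were seen. Rpl22 averaged 639 normalized counts in heterozygous, 725 in mutant and 903 in wild-type IP. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives were a pseudocount of 8, no filter, a minimum mean of 100, and upper-quartile and quantile rescaling of the group means.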

Results

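Ribosome-bound RNA of GABAergic neurons and whole-lysate RNA were measured in mouse cortex at postnatal day 7.5, in a design that asks how loss of the kinases ERK1 (gene Mapk3) and ERK2 alters inhibitory neurons. Cre recombinase driven from the Slc32a1 locus, which encodes the vesicular GABA transporter, switched on an HA-tagged ribosomal protein Rpl22 in GABAergic neurons, and antibody to the tag pulled down their ribosomes (the IP). Whole lysate from the same cortices served as input. The 16 libraries fell into 6 groups. Mutant cortices lacked Erk1 and carried 2 floxed Erk2 alleles (3 IP and 3 input libraries). Heterozygous cortices lacked Erk1 and carried 1 floxed and 1 wild-type Erk2 allele (3 and 3). Cortices whose labels list no Erk allele, called wild type here, gave 2 IP and 2 input libraries. The values analysed are the authors' mean normalized count of each group for 12009 genes, with no value per library, so raw depth and the spread within a group are unknown. The mean normalized counts summed to between 10866900 in wild-type input and 11956500 in mutant IP. Errors below are standard errors (SE) implied by the authors' own fold changes and p-values, and adjusted p-values come from the reconstructed Wald test with Benjamini-Hochberg adjustment.

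The Erk1 gene was examined first. Mapk3 (ENSMUSG00000063065, GRCm38 chromosome 7, 126759601 to 126765819) had a mean of 1179 normalized counts in wild-type input, 26.1 in heterozygous input and 14.5 in mutant input. In the IP, Mapk3 stood at 1779, 151 and 116 in the same order. The heterozygous to wild-type difference in Mapk3 was a log2 fold change of -4.53 (SE 0.53, adjusted p = 1.4e-13) in input and -2.95 (SE 0.53, adjusted p = 7.1e-05) in the IP. Cre itself averaged 141 normalized counts in heterozygous IP, 99.2 in mutant IP and 159 in wild-type IP, against 38.8, 17.5 and 31.5 in input.

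The IP carried the transcripts of inhibitory neurons and was poor in those of excitatory neurons and glia. Slc32a1 (chromosome 2, 158610767 to 158615748) was 20.9-fold higher in the IP than in input in heterozygous, 32.4-fold in mutant and 18.2-fold in wild-type cortex. Of the 15 measured pan-GABAergic genes, 14 were enriched in all 3 genotypes, with a median log2 fold change of 2.38. Of the 20 glutamatergic neuron genes, 11 were depleted in all 3 genotypes, with a median of -1.07. Across all genes, 710 were enriched and 793 depleted in every genotype, and none passed in opposite directions in any pair of genotypes.

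Among inhibitory neuron genes, Gad1, which makes GABA from glutamate, was enriched by a log2 fold change of 2.17 (SE 0.27) in heterozygous, 2.51 (SE 0.27) in mutant and 2.47 (SE 0.32) in wild-type cortex. The neuropeptide gene Npy was enriched by 3.87 (SE 0.36), 4.53 (SE 0.36) and 4.86 (SE 0.43) in the same order. Of 19 genes of interneurons from the medial ganglionic eminence, 7 were enriched and 1 was depleted in all genotypes, and camera gave an adjusted p of 1.2e-05. Of 18 genes of interneurons from the caudal ganglionic eminence, 6 were enriched (adjusted p = 1.8e-05), among them Calb2, Tac2, Crh and Reln. The pan-GABAergic list gave an adjusted p of 3.8e-20. Cytosolic ribosomal protein mRNAs were also enriched, with 19 of 64 passing in all genotypes (median 1.35, adjusted p = 9.0e-13). Other transcripts with large mean enrichments were Lars2, a mitochondrial leucyl-tRNA synthetase, at log2 4.88 (SE 0.41) in heterozygous, 5.01 (SE 0.41) in mutant and 4.14 (SE 0.48) in wild type, and Sptb, a spectrin, at 4.13 (SE 0.36), 4.26 (SE 0.36) and 4.64 (SE 0.42).

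Depleted transcripts included Rorb, a layer 4 transcription factor, at log2 -2.87 (SE 0.32) in heterozygous, -2.77 (SE 0.32) in mutant and -2.49 (SE 0.38) in wild type. The water channel gene Aqp4 of astrocytes was depleted by -2.41 (SE 0.28), -2.84 (SE 0.28) and -2.77 (SE 0.34). The camera test gave adjusted p-values of 4.5e-11 for glutamatergic neuron, 1.2e-05 for astrocyte, 5.7e-06 for oligodendrocyte lineage, 0.0020 for microglia, 0.0064 for vascular and meningeal and 0.0093 for cell cycle genes. Members depleted in all 3 genotypes numbered 5 of 16 astrocyte, 4 of 13 oligodendrocyte lineage, 2 of 11 microglia, 2 of 20 vascular and 3 of 14 cell cycle genes. GABA-A receptor subunits were depleted, 8 of 12, with 1 enriched (adjusted p = 3.2e-06), Gabra5 among them at -2.29 (SE 0.31), -2.19 (SE 0.31) and -2.09 (SE 0.37). Activity-dependent late response genes were higher (8 of 23 enriched, 2 depleted, adjusted p = 0.015), a call that was lost at a preset correlation of 0.05 (adjusted p = 0.075). The other lists did not pass. Adjusted p-values were 0.10 for ERK feedback and target genes, 0.77 for ERK pathway components, 0.49 for immediate early genes, 0.76 for ionotropic glutamate receptor subunits, 0.12 for voltage-gated ion channels, 0.24 for p53 target and apoptosis genes and 0.10 for ATF4 and unfolded protein response genes. The erythroid list had 4 measured members and the Y-linked list 3, too few for the test.

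**Figure D1:**
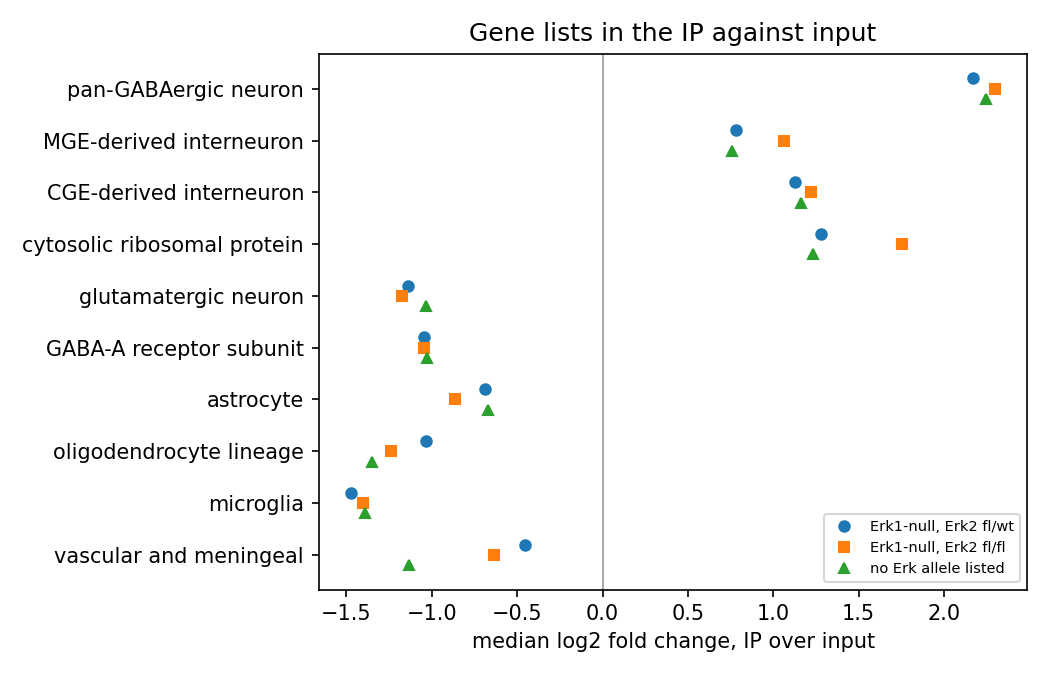
Median log2 fold change of IP over input for 10 gene lists (vertical axis) in each genotype (symbols), from the authors' fold changes. Inhibitory neuron and ribosomal protein lists lie above 0 and lists of other cell types below 0 in every genotype, with pan-GABAergic medians of 2.17 in heterozygous, 2.30 in mutant and 2.24 in wild type.

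Within the IP, few genes passed between mutant and heterozygous cortices once all genes were taken into account. The simulated test called 14% of genes changed by a log2 fold of 1, so a low count does not show that few genes differ. Of 11985 genes tested, 3 were higher and 5 lower in the mutant at an adjusted p under 0.05. The largest decreases were in Cecr2, a chromatin remodelling factor (chromosome 6, 120666369 to 120771190), and Prlr, the prolactin receptor. Cecr2 had means of 141 in heterozygous and 20.4 in mutant IP (log2 fold change -2.39, SE 0.47, adjusted p = 0.0048). Prlr had 81.9 and 10.4 (-2.38, SE 0.54, adjusted p = 0.022).

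Decreases were also seen in Cpt1a, a carnitine palmitoyltransferase of fatty acid oxidation, at -1.55 (SE 0.35, adjusted p = 0.019), and Fndc1 at -1.60 (SE 0.37, adjusted p = 0.031). The increases were in Nova2, a neuronal splicing factor, at 0.74 (SE 0.17, adjusted p = 0.034), in Jhy at 3.04 (SE 0.64, adjusted p = 0.0088) and in Phactr2 at 2.00 (SE 0.44, adjusted p = 0.015). Jhy and Phactr2 are not among the genes of the authors' deposited table of IP differences, whose reason for leaving them out is not stated, and a test on group means cannot see whether 1 library set the mean. In wild-type IP, Cecr2 stood at 43.6, Prlr at 42.0 and Cpt1a at 69.3, between the mutant and heterozygous means. For Cpt1a, wild type was 0.374 times the heterozygous level and mutant 0.318 times, so the wild-type mean lay beside the mutant one. The same 2 ratios were 0.314 and 0.151 for Cecr2, and 0.518 and 0.138 for Prlr. In total 582 genes, or 4.86% of those tested, had an unadjusted p under 0.05, no more than that threshold gives by chance alone. With a pseudocount of 8, 3 genes passed, and with a minimum mean of 100, 5 did.

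The authors' deposited table lists 447 genes for this comparison, 256 higher and 191 lower in the mutant. Its values show an unadjusted p below 0.05, a fold change of at least 1.5 in either direction and a mean of at least 50 in either group. No adjusted p is in it. In the reconstruction, the share of genes under that unadjusted p was no more than chance alone gives. Even at the highest value that adjustment over 12009 genes allows, 6 of the 447 had an adjusted p of at most 0.05 (among them Cecr2, Cpt1a, Fndc1, Prlr and Nova2). The largest listed increases in the authors' deposited table included Cartpt, a neuropeptide gene, at log2 2.26 (p = 0.00037) and Pdlim3 at 2.03 (p = 0.00071). The largest decreases in the authors' deposited table included Egr2 at -2.07 (p = 0.0023) and Adam4 at -1.99 (p = 0.0030).

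Listed genes of the ERK pathway went both ways. Of 16 ERK feedback and target genes that could have been listed, 3 were listed as lower, against 0.269 expected (Fisher's exact test p = 0.0022, adjusted p = 0.043 over 38 tests). In the authors' deposited table these were Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, at -1.36 (p = 0.00021), Etv5 at -0.90 (p = 0.015) and Spred2 at -0.61 (p = 0.012). Fosl2 of the same list was higher at 0.98 in the authors' deposited table, and of 24 ERK pathway components 1 was listed as higher and none as lower. Of 22 activity-dependent late response genes, 4 were listed as higher against 0.497 expected (Fisher's exact test p = 0.0013, adjusted p = 0.043). These were Sst, Bdnf, Nrn1 and Rgs2, at 0.90, 1.13, 1.44 and 0.63 in the authors' deposited table, while Crh was listed as lower at -1.32. Sst averaged 7101 normalized counts in heterozygous, 13847 in mutant and 13223 in wild-type IP, so that the wild-type mean lay beside the mutant one. The camera test over all measured values passed for none of 19 lists, with an adjusted p of 0.18 for ERK feedback and target genes and 0.13 for late response genes. For the lists of other cells it gave 0.24 for glutamatergic neuron, 0.23 for astrocyte, 0.48 for oligodendrocyte lineage, 0.44 for microglia and 0.44 for vascular genes. Adjusted over the list alone, 1 ERK feedback and target gene passed as higher and 1 as lower. Both Fisher's exact tests treat genes as independent, which they are not, so their p-values may be too small.

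Y-linked genes were higher in mutant cortex. In the IP, Ddx3y rose by a log2 fold change of 1.44 (SE 0.51) and Eif2s3y by 1.09 (SE 0.48), and 2 of the 3 Y-linked genes passed when adjusted over the list alone. In input, Kdm5d rose by 1.47 (SE 0.57) and passed when adjusted over the list alone. None passed over all genes. The labels used here do not give the sex of the animals, and the proportion of males can differ between these groups.

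In input, immediate early genes and ERK targets were higher in mutant than in heterozygous cortex as groups. Of 16 activity-dependent immediate early genes, 14 had a log2 fold change above 0, with a median of 0.49 (camera adjusted p = 1.8e-06). Of 16 ERK feedback and target genes, 12 were above 0, with a median of 0.29 (adjusted p = 0.00067). Ribosomal protein mRNAs were lower, 48 of 61 below 0 with a median of -0.54 (adjusted p = 2.4e-06). Their level depended on scaling. The median log2 ratio of the group means over 64 of these genes was -0.69, and -0.23 (-0.48 to 0.0073, 2 standard errors either way) after quantile normalization, where the camera adjusted p was 0.010. The immediate early gene Fos had means of 15.7 in heterozygous and 118 in mutant input. In heterozygous against wild-type input, immediate early genes were lower (median -0.34, camera adjusted p = 0.00091). Part of their difference between mutant and heterozygous input may thus lie in the heterozygous group. ERK feedback and target genes did not pass in heterozygous against wild-type input (median -0.079, camera adjusted p = 0.15).

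Fos had a log2 fold change of 2.25 (SE 0.58) and passed when adjusted over the list alone, but not over all genes (adjusted p = 0.18). Over all 11947 genes tested, 4 were lower and none higher. These were the tubulin folding cofactor Tbca at -1.43 (SE 0.29, adjusted p = 0.0081), the ribosomal stalk gene Rplp1 at -2.36 (SE 0.52, adjusted p = 0.026), Crhbp at -2.20 (SE 0.49, adjusted p = 0.026) and BC029722 at -2.59 (SE 0.60, adjusted p = 0.046). BC029722 had a mutant mean of 0.497, close to the floor. In total 445 genes, or 3.72% of those tested, had an unadjusted p under 0.05, no more than that threshold gives by chance alone. After quantile normalization of the group means none of the 4 passed, and with a pseudocount of 8 only 1 gene did. Genes of medial ganglionic eminence interneurons were lower (median -0.27, adjusted p = 0.041) and late response genes higher (median 0.12, adjusted p = 0.030), and both calls were lost at a preset correlation of 0.05 (adjusted p = 0.16 for each). The 3 calls that held there were those of immediate early genes (adjusted p = 0.00029), ERK feedback and target genes (0.011) and ribosomal protein genes (0.010). Of the other cell types, astrocyte genes gave an adjusted p of 0.17 and vascular and meningeal genes 0.11.

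The difference between the IP and input effects of genotype was tested directly. ERK feedback and target genes were lower in mutant IP relative to mutant input than in heterozygous cortex, with a median log2 difference of -0.35 and 10 of 16 members below 0 (camera adjusted p = 0.00013). Immediate early genes were lower by the same measure, 10 of 16 with a median of -0.17 (adjusted p = 0.0060). In the IP alone, immediate early genes were not lower, with a median of 0.23 and 9 of 16 above 0 (camera adjusted p = 0.48). ERK feedback and target genes had a median of -0.090 in the IP alone (camera adjusted p = 0.18). Both differences therefore include the higher level of these lists in mutant than in heterozygous input. Ribosomal protein genes were higher, 50 of 64 with a median of 0.62 (adjusted p = 3.4e-05, and 0.0036 after quantile normalization), a difference that includes their scaling-dependent decrease in input.

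Spry4 showed the pattern, with a mean of 175 in heterozygous and 63.3 in mutant IP, against 150 and 270 in input. Its difference was -2.15 (SE 0.52), which did not pass over all genes (adjusted p = 0.13). Etv5 had a difference of -1.97 (SE 0.52, adjusted p = 0.35) and Spred2 of -0.996 (SE 0.34, adjusted p = 0.93). Adjusted over the list alone, these 3 of the 16 members passed. Of all 12009 genes tested, Tbca at 1.92 (SE 0.41, adjusted p = 0.023) and Cecr2 at -3.09 (SE 0.67, adjusted p = 0.023) passed, and neither did with a pseudocount of 8. After quantile normalization of the group means, Cecr2 was the 1 gene that passed. In total 465 genes, or 3.87% of those tested, had an unadjusted p under 0.05, no more than that threshold gives by chance alone. Genes of medial ganglionic eminence interneurons (adjusted p = 0.028) and of astrocytes (adjusted p = 0.043) passed, but not at a preset correlation of 0.05 (adjusted p = 0.14 and 0.15). Glutamatergic neuron genes did not pass (adjusted p = 0.50).

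**Figure D2:**
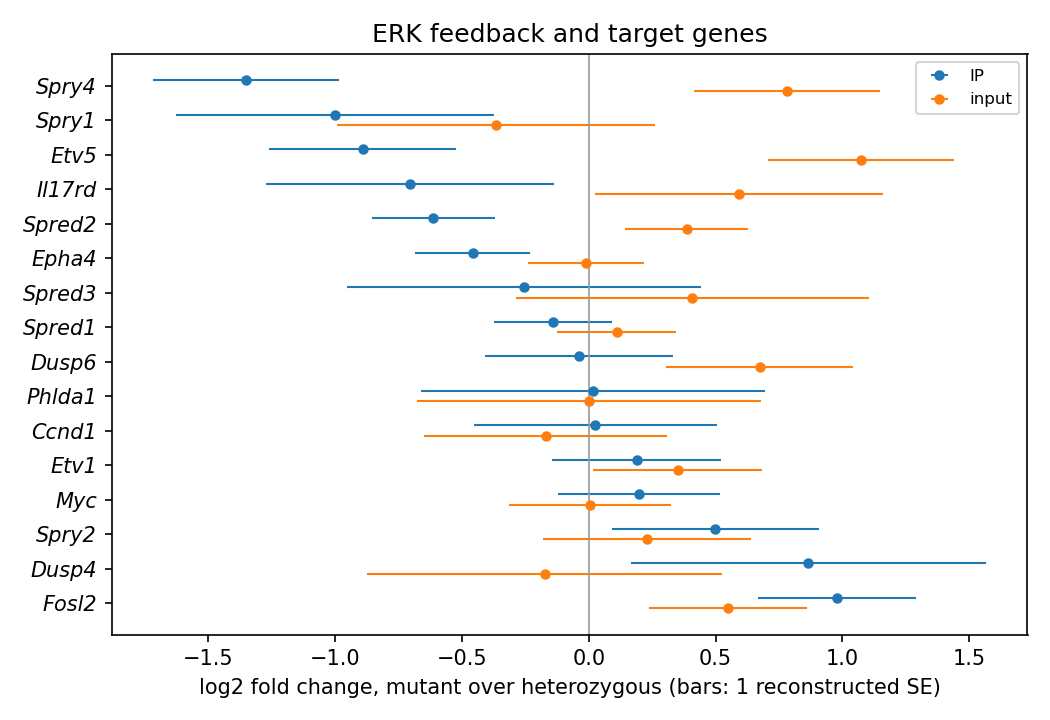
Log2 fold change of mutant over heterozygous (horizontal axis) for the 16 ERK feedback and target genes (vertical axis, ordered by the IP value) in the IP and in input. Bars are 1 reconstructed SE. Spry4 lies at -1.35 in the IP and 0.78 in input, and Etv5 at -0.89 and 1.07.

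The heterozygous and wild-type groups differ by loss of Erk1 together with 1 floxed Erk2 allele. Their sample titles also fall into separate series, LF and WT. Differences of line or cohort therefore cannot be told apart from those of the alleles. In the IP, Ank3, which encodes ankyrin-G of the axon initial segment, had a log2 fold change of 1.78 (SE 0.30, adjusted p = 3.0e-05), with means of 44935 in heterozygous and 12282 in wild-type IP. Utrn, which encodes utrophin, rose by 1.34 (SE 0.24, adjusted p = 6.5e-05). In total 9 genes were higher and 1, Mapk3, was lower among 11985 tested.

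The other genes that rose were Card6, which was listed at 0 in wild-type IP and at 31.2 in heterozygous IP, Iqgap1 at 1.65 (SE 0.33, adjusted p = 0.0019), Kat6a at 1.39 (SE 0.31, adjusted p = 0.017), Nipbl at 1.75 (SE 0.41, adjusted p = 0.030), Mtm1 at 1.96 (SE 0.46, adjusted p = 0.030), 4930447C04Rik at 1.92 (SE 0.46, adjusted p = 0.037) and the zinc transporter gene Slc30a5 at 1.25 (SE 0.29, adjusted p = 0.030). Card6 was at the floor in wild-type IP, so its ratio rests on the pseudocount of 1 and its call is uncertain. Quantile normalization of the group means gave 18 genes and a pseudocount of 8 gave 6. All 15 pan-GABAergic genes had lower heterozygous than wild-type means (median -0.26, adjusted p = 0.040). Genes of medial ganglionic eminence interneurons (median -0.31, adjusted p = 0.015), astrocyte genes (-0.28, 0.040), late response genes (-0.12, 0.040) and ERK feedback and target genes (13 of 16 below 0, -0.29, 0.040) were lower as well, while vascular and meningeal genes (0.59, 0.015) and cell cycle genes (0.42, 0.040) were higher. None of these 7 lists passed at a preset correlation of 0.05, where the pan-GABAergic adjusted p was 0.15, or after quantile normalization.

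In input, Rpl15 (chromosome 14, 18267823 to 18271391) was higher in heterozygous than in wild-type cortex, with means of 4371 and 618 (log2 fold change 2.66, SE 0.33, adjusted p = 9.0e-12). It was also high in mutant input, at 5650, and in the IP the means were 2966 in heterozygous, 4281 in mutant and 1708 in wild type. Rpl15 and Mapk3 were the 2 genes that passed in input among 11947 tested. There, 175 genes (1.46%) had an unadjusted p under 0.05, fewer than that threshold gives by chance alone. The z values had an SD of 0.74. The reconstructed SE may thus be too large in this comparison, and the low count does not show that few genes differ. Astrocyte genes were lower, 15 of 16 below 0 with a median of -0.32 (camera adjusted p = 3.0e-05), as were oligodendrocyte lineage genes, 12 of 13 with a median of -0.37 (adjusted p = 0.00091), and immediate early genes, 12 of 16 with a median of -0.34 (adjusted p = 0.00091). These 3 lists also passed at a preset correlation of 0.05. The calls of vascular and meningeal, GABA-A receptor and ribosomal protein genes did not hold there (adjusted p = 0.13, 0.13 and 0.25).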

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

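The tests of the 447 listed genes and of GABAergic material, and the limits used for the length and GC tests, were chosen after the results were seen. The test by quantile normalization was fixed before its result was computed, although each pattern itself was noticed in the data. Values per library would be needed to look for single outlying samples, so no such search was made.

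Tbca and Cecr2 stand out because the effect of genotype differed between IP and input by a direct test. Tbca had a log2 difference of 1.92 and Cecr2 of -3.09.

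The first pattern is the set of 447 genes that the authors' deposited table lists between mutant and heterozygous IP. Position was set on a scale from 0 at the mutant to 1 at the heterozygous mean. For chance differences, wild-type means would lie midway, at 0.5, only if nothing else set the wild-type libraries apart. These libraries belong to another title series, so their position cannot decide whether the differences were chance. The median position was 0.596 (95% bootstrap interval over genes 0.528 to 0.644), but it was 0.70 for genes higher and 0.43 for genes lower in the mutant, on opposite sides, and genes are not independent, so the interval was not taken to exclude chance. That reading was adopted after these 2 values were seen. Carry-over of other cells' RNA also stays open, since Spearman's rho with wild-type enrichment was 0.095 (interval -0.0045 to 0.19), and an effect of Erk2 loss stays open as well.

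The second pattern is the lower level of ribosomal protein mRNAs in mutant input, with an uncorrected median log2 ratio of -0.69 (-0.95 to -0.42, 2 standard errors either way). This is the plain ratio of group means over 64 genes, whereas the median of -0.54 in the list test is of fold changes shrunken as in the authors' table, over the 61 genes that passed the filter. Other genes had a median of -0.10, so relative to them it was -0.58. After the GC trend of other genes was subtracted, the median relative to them was -0.61 (-0.88 to -0.34), against -0.58 before. GC content as the whole cause is argued against, since this range lies below 0.5 times the uncorrected relative value (-0.29). The range is over genes that are not independent, however, and may be too narrow. Against 0.5 times the uncorrected median not set relative to other genes, the limit first fixed, the range would have fallen just short. After the length trend was subtracted the median was -0.43 (-0.67 to -0.19), and after quantile normalization -0.23 (-0.48 to 0.0073). These 2 ranges include 0.5 times the uncorrected value, so transcript length and library scaling are not excluded, and genotype cannot be told apart from them.

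The third pattern is the abundance of spectrin, ankyrin and plakin mRNAs in the IP, for 16 genes chosen by family after several had been seen. After the length trend was removed, the median wild-type enrichment was 1.63 (0.97 to 2.30), against 1.34 relative to other genes before. Length here was the median over each gene's annotated transcripts, with a median of 3024 bases for this family. The expressed transcripts can be longer or shorter, so the test cannot exclude transcript length as a cause. The 16 genes were higher in heterozygous than wild-type IP (median 1.40), while the pan-GABAergic median was -0.28 (-0.42 to -0.15). More GABAergic material in the heterozygous IP is therefore argued against as the cause, for these libraries only. The range is over genes, which are not independent, and leaves out variation between libraries. Binding of such mRNAs in the pull-down and an effect of the Erk alleles were not tested and stay open.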

How the results depend on the processing

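The preset correlation of 0.05, ranks, the mean of genotypes as 1 contrast and the limits on the authors' list were chosen after the data were seen. No paired analysis was possible because the deposited columns are group means, although IP and input of the same number share a lysate. For the same reason leaving out replicates, fits of all or of 2 groups, limma with and without a trend, count models, an estimated correlation, fry and other splits of the samples were not run. Of the alternative list values, 745 kept their side of the threshold, 44 lost it and 5 gained it. Of the named gene values, 1196 kept it and 21 lost it. None reversed. The cause of the changes below was not tested, except that fewer or more genotypes enter by construction.

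IP against input gave 1503 genes called in all 3 genotypes, 3094 in heterozygous alone and 4445 in mutant alone. The planned mean of the 3 genotypes as 1 contrast gave 6456. The mutant to heterozygous IP count of 8 became 3 with a pseudocount of 8 and 5 at a mean of at least 100. The authors' 447 genes became 152 at a p of at most 0.01 and 6 at the highest possible adjusted p. The input count of 4 became 1 with a pseudocount of 8, 1 at a mean of at least 100 and 0 after quantile normalization, and its 5 lists became 3 without the filter, 3 at a mean of at least 100, 3 at a preset correlation of 0.05 and 3 with ranks. The heterozygous to wild-type IP count of 10 became 6 with a pseudocount of 8 and 18 after quantile normalization, and its 7 lists became 3 with a pseudocount of 8, 0 after quantile normalization, 0 at a preset correlation of 0.05 and 4 with ranks. The 6 lists of the heterozygous to wild-type input comparison became 3 at a preset correlation of 0.05. The difference of IP and input effects, with 2 genes, gave 0 with a pseudocount of 8 and 1 after quantile normalization, and its 5 lists became 3 after quantile normalization and 3 at a preset correlation of 0.05.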

Other observations

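The test of genes near Mapk3 in input was fixed before its result was computed, and the same test in the IP was chosen after its values were seen. The other values in this part were looked at after the data were seen and carry no test of their own.

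The spectrin gene Sptbn1 was 3.74-fold higher in heterozygous than in wild-type IP and 27.9-fold higher in the IP than in input in heterozygous cortex. The 3 most abundant genes of a group took 11.3% of the summed mean normalized counts in heterozygous IP, 7.94% in mutant IP and 4.21% in wild-type IP, against 2.60%, 2.71% and 2.74% in input.

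A hypothesis was that strain variants linked to the Erk1 null allele alter genes around Mapk3. Within 10 Mb of Mapk3, 2 of 153 genes had an unadjusted p under 0.05 between heterozygous and wild-type input, against 172 of 11791 elsewhere (odds ratio 0.895, 95% interval 0.107 to 3.34, Fisher's exact test p = 1.0). No excess was found, but the interval includes an odds ratio of 2, which leaves an excess in input open. In the IP the counts were 6 of 154 near Mapk3 and 654 of 11828 elsewhere (odds ratio 0.693, 95% interval 0.249 to 1.55, Fisher's exact test p = 0.48). The upper bound under 2 argues against an excess of that size in the IP, although linked variants may still act on single genes.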
